A study of Mus musculus with 6 samples.

How the data were processed

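RNA was measured in 6 libraries of sorted bone marrow cells from C57BL/6 mice, 3 WT and 3 NHD13. Per the labels' protocols, marrow was taken, cells were sorted by FACS, RNA was extracted with Trizol and libraries were made with a standard Illumina procedure, and the series states an Illumina HiSeq instrument. The deposited table holds raw counts, whole numbers per gene and library that the authors did not normalise. Per the submitters' processing notes, Bowtie2 2.2.1, HTSeq 0.5.4p3 and the mouse build mm10 were used. The gene annotation, the strand setting and the read filters are not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart. The columns were matched to samples by the letters and the replicate number in their names, the NHD13 columns by the initial N and the number. The table has 17523 entries, of which 719 were 0 in every library and 0 named no gene, and none of its columns was left out.

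Total counts per library ran from 12541538 (WT replicate 1) to 14388772 (NHD13 replicate 2), so that a count of 0 allowed up to 0.208 to 0.239 CPM per library at a floor of 3 counts. Floors and intervals cover counting error only, since the reads carry no molecular identifiers. For genes with 1 to 3 counts in a group the ratio has an exact (Clopper-Pearson) 95% counting interval, and for genes at 0 the fold is a bound against 3 counts over the group. Replicates were compared by a chi-square of their counts over genes with a summed count of at least 10, without the ribosomal RNA gene Rn45s. The chi-square per degree of freedom was 3.459 between NHD13 replicates 2 and 3, 28.57 and 28.11 between NHD13 replicate 1 and these, and 4.643 to 13.01 between WT libraries. Across groups it was 20.65 between NHD13 replicate 1 and WT replicate 1, lower than between NHD13 replicate 1 and its own group, and 35.34 to 52.92 for the other pairs. By Spearman's correlation NHD13 replicate 1 was closer to NHD13 replicates 2 (0.989) and 3 (0.9884) than to WT replicate 1 (0.9859). So no pair differed by as little as sampling noise and all 6 libraries were kept apart.

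The comparison of NHD13 with WT used edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, which left 12013 genes and set 5510 aside, and libraries were scaled by TMM. The quasi-likelihood F test (estimateDisp, glmQLFit with robust estimation, glmQLFTest) had the group as its term, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. All tests were two-sided unless stated. The standard error is the log2 change divided by the square root of F. CPM values are TMM-scaled and given as mean ± SD over 3 libraries. A principal component analysis used log2 CPM with a prior count of 2.

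Before the data were examined, 40 gene lists were fixed: the 4 Hox clusters, Hox cofactors, HOX and MEIS targets in leukaemia, fetal stem cell genes, markers of long-term HSCs and multipotent progenitors, genes of granulocyte-monocyte progenitors, mature neutrophils, monocytes and macrophages, erythroid cells, megakaryocytes and platelets, mast cells with basophils and eosinophils, B-lymphoid cells, T and NK cells, dendritic cells and stromal and endothelial cells. The others were S-phase, G2-M, CDK inhibitor and quiescence genes, p53 targets, apoptosis regulators, interferon response, NF-kB and inflammatory, immediate early, heat shock and chaperone, ribosomal protein, ribosome biogenesis, oxidative phosphorylation, glycolysis, MDS and AML driver genes, leukaemia stem cell surface antigens, DNA repair, TGF-beta, adhesion and homing, Wnt and Notch genes, lineage transcription factors and sex genes. In the table, 3 members were found by an older symbol and 24 entries were not found. Lists with at least 5 tested members, 36 in all, were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and adjusted over the 36. The sex genes were described as values, and 3 lists were below the minimum. Counts of members past the threshold were also taken with p-values adjusted over the list alone.

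The rule for the genes named, also fixed beforehand, takes Nup98 and Hoxd13, the 10 genes with the largest change in each direction among those past the threshold with an average log2 CPM of at least 2, libraries that do not overlap between groups and a symbol that is not a clone or predicted-gene name. It further takes the 5 with the lowest p in each direction, up to 4 members of each list with the lowest p (or the 2 most abundant where none passed), and any Hox, cofactor or sex gene. It selected 168 genes. Gene positions come from GENCODE vM21 (GRCm38, which is mm10), matched by symbol for 16301 entries and by an older symbol for 962, with 260 not matched. Of 167 genes selected by the rule with a position, 37 overlap another gene, 31 of them on the other strand, and the counts of such genes are uncertain.

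The alternatives fixed beforehand were DESeq2 size factors, upper-quartile factors and total counts in place of TMM, TMM on totals without the 20 most abundant genes, no filter on low counts, a filter of 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom and estimation without the robust option. Further ones were the replicate number as a block, a test against a 1.5-fold change, an adjusted p under 0.01, leaving out each library, and for lists fry and camera with an estimated correlation. Alternatives without genes on chromosomes X and Y, without replicate 1 of both groups and with the Y-linked share of counts as a covariate were added after seeing the data. The procedures were tested on simulated counts for the same 12013 genes with 200 changed. The edgeR fit recovered 68.66% of genes changed 1.5-fold, 82.09% of those changed 2-fold and 100% of those changed 4-fold, and 19 of its 186 calls (10.2%) were false, above the nominal 5%, against 12.4% for DESeq2. Of 38 simulated lists, both changed lists were called and 0 of the others by camera. The simulated genes were drawn independently of each other. The result therefore says nothing of camera where members of a list move together, with estimated correlations of 0.717 for erythroid and 0.806 for S-phase genes. Figures and tables used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Results for some genes of the lists are not reported here.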

Results

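Gene expression was measured by RNA sequencing of cells sorted by FACS from the bone marrow of C57BL/6 mice. The series describes the cells as hematopoietic stem cells (HSCs), and the surface markers used for the sort are not given in the sources used here. Wild-type (WT) mice were compared with NHD13 mice, which carry a fusion of the nucleoporin gene NUP98 with the homeobox gene HOXD13 and serve as a model of myelodysplastic syndrome, a disorder of blood formation that can progress to leukaemia. The question was how expression of the fusion changes the transcriptome of these cells. There were 3 WT and 3 NHD13 libraries. Total counts were 12541538, 13534544 and 14308040 for WT replicates 1 to 3 and 13517547, 14388772 and 14383201 for NHD13 replicates 1 to 3, so that 1 count corresponded to between 0.0695 and 0.0797 CPM, the count scaled to the library total. Nothing in the labels says that the replicates came from separate animals, and the p-values therefore measure only the spread between these libraries.

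The fusion was read first as a check of the labels. The deposited table has a row named for the fusion, NUP98-HOXD13, which held 0 counts in all 3 WT libraries and 185, 179 and 167 counts in NHD13 replicates 1, 2 and 3. This was 12.6 CPM ± 1.18 (SD, n = 3) and at least 170-fold higher than a floor of 3 counts over the WT group. Mouse Nup98 (mm10 chromosome 7, 102119398 to 102210176) was at 67.4 CPM ± 5.84 in WT and 78.4 CPM ± 1.12 in NHD13 (n = 3 each), a log2 change of 0.22 (SE 0.08) that did not pass the threshold (edgeR quasi-likelihood adjusted p = 0.0609). It passed without WT replicate 1 (adjusted p = 0.0318) or NHD13 replicate 1 (0.0329). Mouse Hoxd13 had 0 counts in every library, which allows up to 0.239 CPM in the shallowest one.

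Of 12013 genes tested, 1799 were higher and 1839 were lower in NHD13 than in WT at an adjusted p under 0.05, or 30.3% of the tested genes. At least a 2-fold change was seen for 251 of the higher and 680 of the lower genes. Every library of one group lay above every library of the other for 46.1% of the tested genes, where chance gives 10%. The first principal component of the log2 CPM values held 75.6% of the variance and separated the groups, and the second, with 12.3%, set NHD13 replicate 1 (28.2) apart from NHD13 replicates 2 (-9.44) and 3 (-14.1). The counts depended on single libraries. Without NHD13 replicate 1, 3012 genes were higher and 2966 lower. These were 828 and 957 without WT replicate 2, 806 and 978 without WT replicate 3, 760 and 1069 without NHD13 replicate 2, and 836 and 1104 without NHD13 replicate 3. The libraries also differed in Xist and Y-linked RNA. With the Y-linked share as a covariate, a setting chosen after seeing the data, 111 genes were higher and 175 lower. Of 158 genes past the threshold that the naming rule selects, 69 stayed past it with this covariate and 89 did not, among them Eif2s3y, Kdm5d and Uty, which are part of the covariate. Over 3514 changed autosomal genes a median of 99.1% of the log2 change was left with the covariate. Their median SE went from 0.118 to 0.191, as 57.8% of the variance of the covariate lay between the groups. Upper-quartile scaling gave 1427 higher and 2132 lower genes.

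Genes of all 4 Hox clusters, which encode homeobox transcription factors that pattern the body axis and regulate blood progenitors, were higher in NHD13. All 8 tested HoxA genes rose (8 adjusted over the list alone), with a median log2 change of 3.24. Hoxa9 (chromosome 6, 52223100 to 52231089) went from 6.22 CPM ± 0.998 to 39.4 CPM ± 1.07, a 6.34-fold rise (log2 2.66, SE 0.12, adjusted p = 1.56e-05). Hoxa10 went from 0.822 CPM ± 0.281 to 20.2 CPM ± 4.82 (24.5-fold, adjusted p = 5.53e-05), Hoxa7 from 3.65 to 20.4 CPM and Hoxa5 from 1.36 to 12.2 CPM. The call of Hoxa4 (adjusted p = 0.0398) was lost without WT replicate 2 (adjusted p = 0.146), WT replicate 3 (0.141), NHD13 replicate 2 (0.0924) or NHD13 replicate 3 (0.107). Hoxa11 had 0 counts in every library.

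In the HoxB cluster, 4 of 5 tested genes rose (4 adjusted over the list alone). Hoxb8 went from 0.0496 CPM ± 0.0432 to 6.55 CPM ± 2.01 (adjusted p = 0.000141), and Hoxb6, Hoxb7 and Hoxb3 rose as well. Among the HoxB genes too low to test, Hoxb5 had 2 counts in WT and 54 in NHD13, and Hoxb2 had 9 in WT and 0 in NHD13. Hoxb4, between Hoxb3 and Hoxb5 on chromosome 11, was at 6.88 CPM ± 0.419 in WT and 6.85 CPM ± 1.44 in NHD13 (log2 -0.01, SE 0.18, adjusted p = 0.978). Its log2 change was 0.04 without WT replicate 3, 0.13 without NHD13 replicate 2 and 0.34 with the covariate, none past the threshold. All 4 tested HoxC genes rose from near the detection limit (4 adjusted over the list alone). Hoxc4 (chromosome 15, 103018934 to 103036852) had 0 counts in WT and 9.08 CPM ± 0.92 in NHD13, at least 123-fold above a floor of 3 counts over the WT group. Hoxc5 had 2 counts in WT and 718 in NHD13, a ratio of 344 with a 95% counting interval of 94.9 to 2850, and Hoxc6 reached 10.3 CPM ± 1.02 and Hoxc8 1.72 CPM ± 0.71. Both tested HoxD genes rose (2 adjusted over the list alone), with Hoxd8 at 0 counts in WT and 2.11 CPM ± 1.14 in NHD13 and Hoxd4 at 1 count in WT and 1.08 CPM ± 0.454 in NHD13. With WT near 0, the HoxC and HoxD genes, and Hoxb6, Hoxb7 and Hoxb8, could pass the low-count filter only through NHD13. That every tested HoxC and HoxD gene was higher therefore followed from the filter. Hoxa2, Hoxa3, Hoxa4, Hoxa6 and Hoxa10 also needed NHD13 libraries to pass the filter, since for none of them did all 3 WT libraries reach 10 counts. For these HoxA genes, and for Hoxb6, Hoxb7 and Hoxb8, a fall in NHD13 could hardly have been tested. Only 4 of 7 HoxC and 2 of 6 HoxD genes with a row of counts were tested. Of the rest, Hoxc9 had 0 counts in WT and 8 in NHD13, Hoxc12 and Hoxd3 0 and 1, and Hoxd11 2 and 2. Hoxc10, Hoxd9 and Hoxd13 had 0 in both. Gene models overlap within HoxA (Hoxa3 with Hoxa4, Hoxa5 and Hoxa6), HoxC (Hoxc5 with Hoxc6 and Hoxc8) and HoxD (Hoxd3 with Hoxd4), so the split of reads between these neighbours is uncertain. In the gene set test (camera), HoxA (adjusted p = 2.24e-27) and HoxB (adjusted p = 1.38e-06) passed, and with an estimated correlation HoxA held (adjusted p = 0.0285) and HoxB did not (adjusted p = 0.211). Both sets hold genes that needed NHD13 to enter the test, so their p-values are not separate support for a rise of the clusters. With the Y-linked share as a covariate, 15 of these Hox genes stayed past the threshold and Hoxa4, Hoxd4 and Hoxd8 did not.

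**Figure D1:**
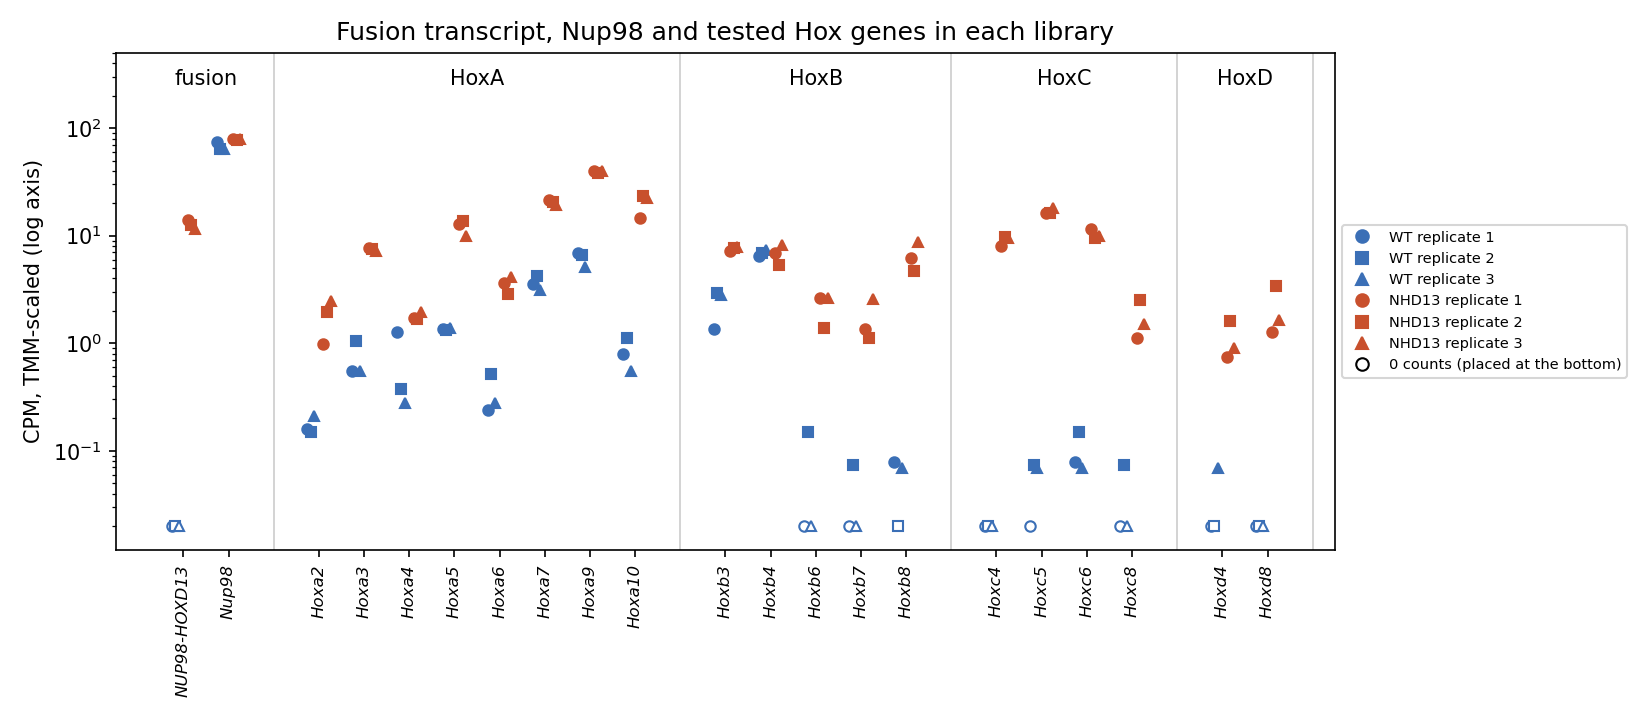
CPM (TMM-scaled, log axis) of the fusion transcript, Nup98 and every tested Hox gene, in each of the 3 WT (blue) and 3 NHD13 (red) libraries, with open symbols at the bottom for 0 counts. The fusion row and Hoxc4 are at 0 counts in all WT libraries and at 12.6 and 9.08 CPM in NHD13, while Hoxb4 is at 6.88 and 6.85 CPM.

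The cofactors that bind DNA with HOX proteins went in both directions. Pbx3 (chromosome 2, 34171457 to 34373142) rose 9.82-fold, from 5.68 CPM ± 0.445 to 55.9 CPM ± 5.8 (log2 3.30, SE 0.12, adjusted p = 4.9e-06). Meis1 fell 2.81-fold, from 12.6 CPM ± 2.27 to 4.5 CPM ± 0.372 (adjusted p = 0.000843). Pknox1 and Pknox2 were not past the threshold. The list as a whole did not pass camera (adjusted p = 0.959, and 0.981 as the adjusted p with an estimated correlation). The call of Meis1 was lost with the Y-linked share as a covariate (adjusted p = 0.051).

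Among genes described as HOX and MEIS targets in leukaemia, 8 of 24 tested rose and 9 fell (9 and 11 adjusted over the list alone). Eya1, a transcriptional coactivator, rose from 2.3 CPM ± 0.265 to 13.4 CPM ± 1.89 (adjusted p = 7.48e-05), and the transcription factor genes Mecom and Prdm16 rose 6.64-fold and 3.28-fold. Flt3, the receptor tyrosine kinase of early progenitors, fell from 43.8 CPM ± 11.5 to 2.75 CPM ± 1.71 (15.8-fold, adjusted p = 0.000229), and Cd34, Sox4 and Bcl2 fell 3.73-fold, 2.12-fold and 3.06-fold. Camera did not pass this list (adjusted p = 0.978, and 0.981 as the adjusted p with an estimated correlation). Of these genes, Sox4 and Bcl2 were not past the threshold with the Y-linked share as a covariate.

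Lin28b, an RNA-binding protein of fetal blood progenitors that blocks let-7 maturation, had one of the largest increases, from 0.129 CPM ± 0.12 to 57.7 CPM ± 12.8 (chromosome 10, 45376620 to 45486395, log2 8.76, SE 0.36, adjusted p = 9.17e-06). Igf2bp3, another fetal RNA-binding protein gene, rose 5.08-fold to 6.44 CPM ± 1.21. Of the 10 tested genes of the fetal stem cell list these were the only 2 that rose, and Hmga2 (1.51-fold) and Grb10 (1.78-fold) fell (2 and 2 adjusted over the list alone). The call of Hmga2 was lost without any one of WT replicates 1, 2 and 3 and NHD13 replicates 2 and 3, and in DESeq2. The list passed camera as higher (adjusted p = 0.0224) with a median log2 change of only 0.01 against a mean of 0.98, and it did not pass without NHD13 replicate 1 (adjusted p = 0.0896) or with an estimated correlation (adjusted p = 0.257). The median was -0.03 under upper-quartile scaling. With the Y-linked share as a covariate, Lin28b and Igf2bp3 stayed past the threshold and Hmga2 and Grb10 did not.

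Apart from the fusion itself, the Hox clusters and Lin28b, the largest increases among genes with an average log2 CPM of at least 2 were in Mab21l2, Neo1 and the stefin A genes. Mab21l2 (chromosome 3, 86545581 to 86548629) had 1 count in WT and 838 in NHD13, a ratio of 803 with a 95% counting interval of 144 to 31800. It lies inside the span of Lrba on the other strand, which was at 42.3 and 69.8 CPM. Since the strand setting of the counting is not stated, the 2 genes' reads may not be fully separated. Neo1, the netrin receptor neogenin, had 3 counts in WT and 366 in NHD13, a ratio of 117 with a counting interval of 39.7 to 570. Its call was lost without replicate 1 of both groups (adjusted p = 0.0599), a setting chosen after seeing the data. The stefin A genes encode intracellular inhibitors of cysteine proteases and lie together on chromosome 16. Stfa1 rose from 1.83 CPM ± 0.416 to 235 CPM ± 106 (adjusted p = 6.39e-05), Stfa3 from 0.446 to 44.7 CPM and Stfa2 from 0.144 to 19 CPM, and reads of these close copies may be shared. The 7 stefin A genes summed to 4.03 CPM ± 0.964 in WT and to 285, 734 and 730 CPM in NHD13 replicates 1, 2 and 3.

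At the same abundance limit, the 10 largest decreases were in Fcer1a, Prss34 and Mcpt8, genes of mast cells and basophils, in Flt3 and Dntt, and in Gspt2, Nrg1, Bmpr1a, Rps4y2 and Abca9. Gspt2, a translation termination factor gene on chromosome X, fell from 8.65 CPM ± 1.05 to 0.171 CPM ± 0.19 (adjusted p = 0.000141). Nrg1, which encodes the growth factor neuregulin, fell from 7.86 CPM ± 1.62 to 0.239 CPM ± 0.0869 (adjusted p = 6.02e-05), and the BMP receptor gene Bmpr1a fell from 8.28 CPM ± 0.943 to 0.422 CPM ± 0.298 (adjusted p = 0.000141). Rps4y2 was matched by an older symbol to Rps4l, annotated as a transcribed processed pseudogene on chromosome 6, and so is not a Y-linked gene. Rps4y2 and Gspt2 have close copies elsewhere in the genome, so their counts are uncertain. The lowest adjusted p-values among the lower genes belonged to Tanc1 (5.55-fold), the actin-binding protein gene Cttn (12.4-fold), the coagulation factor gene F5 (4.79-fold), Sestd1 (7.63-fold) and the adhesion molecule gene Vcam1, which fell from 118 CPM ± 9.81 to 29.6 CPM ± 4.98 (adjusted p = 5.53e-05).

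The libraries held abundant RNA of maturing myeloid cells in both groups. The mature neutrophil list took 4.99% ± 1.01 of all counts in WT and 3.23% ± 0.527 in NHD13 (n = 3 each), and the long-term HSC markers took 0.071% ± 0.00375 and 0.066% ± 0.0043. The most abundant gene was S100a9, named here after its values were seen, with 1.26% of the counts in WT and 0.792% in NHD13. Of 19 tested long-term HSC markers 3 rose and 6 fell (4 and 6 adjusted over the list alone), and camera did not pass the list (adjusted p = 0.767, and 0.846 as the adjusted p with an estimated correlation). Mecom rose from 1.01 CPM ± 0.29 to 6.77 CPM ± 2.12 and Prdm16 rose as well, as did Mllt3 (log2 0.74), chosen after its values were seen, while Tie1, an endothelial and stem cell receptor gene, fell from 13.1 CPM ± 2.7 to 2.39 CPM ± 0.746 and Hlf fell from 15 CPM ± 1.52 to 3.82 CPM ± 2.09. Between 3 and 9 of these markers fell when 1 library was left out, fewest without WT replicate 2 or WT replicate 3, and the call of Hlf was lost with the Y-linked share as a covariate (adjusted p = 0.0817).

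Most tested markers of multipotent progenitors and most tested B-lymphoid genes fell. Of 13 tested multipotent progenitor markers, 12 fell (12 adjusted over the list alone), with a median log2 change of -1.14. Besides Flt3, Dntt, the DNA polymerase that adds bases at antigen receptor joints, fell from 38.1 CPM ± 14.4 to 1.44 CPM ± 0.557 (26.3-fold, adjusted p = 0.000159), Cd27 fell 4.41-fold and Cd34 went from 175 CPM ± 3.12 to 47 CPM ± 17.7. The list passed camera (adjusted p = 8.97e-11) and not with an estimated correlation (adjusted p = 0.195), and 7 members fell without WT replicate 2 or without WT replicate 3. Of 11 tested B-lymphoid genes 7 fell (7 adjusted over the list alone), among them Il7r (3.93-fold), Cd22 (3.77-fold) and Rag2 (4.63-fold), at 1.89 to 4.38 CPM in WT (camera adjusted p = 4.64e-05, and adjusted p = 0.451 with an estimated correlation). Only 4 B-lymphoid genes fell without WT replicate 2 or WT replicate 3, and the calls of Il7r, Cd22 and Rag2 were lost with the Y-linked share as a covariate. Of 12 tested T and NK genes 3 fell (2 adjusted over the list alone), Ncr1, Klrd1 and Il2rb. Camera was not passed (adjusted p = 0.0897) in the full set and passed without WT replicate 1 (adjusted p = 0.00164), NHD13 replicate 1 (0.0362) or NHD13 replicate 3 (0.00834), where 7, 7 and 5 genes fell. By DESeq2 6 genes of this list fell. The covariate ended the calls of these 3 genes as well, and that of Il2rb was lost without WT replicate 2, WT replicate 3, NHD13 replicate 2 or NHD13 replicate 3 and by limma-voom (adjusted p = 0.0636). With an estimated correlation, the adjusted p of this list was 0.747. The gene model of Rag2 overlaps B230118H07Rik and that of Cd27 lies within the span of Vamp1 on the other strand, so their counts are uncertain.

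Genes of mast cells, basophils and eosinophils had the lowest list median, a log2 change of -2.28. Of 14 tested members 12 fell (12 fell and 1 rose adjusted over the list alone). Fcer1a, the alpha chain of the IgE receptor, had 503 counts in WT and 2 in NHD13 (ratio 262, 95% counting interval 72.3 to 2170, adjusted p = 0.000184). Prss34 and Mcpt8, proteases of basophils, went from 160 CPM ± 84.8 to 3.48 CPM ± 2.92 and from 98.5 CPM ± 38.5 to 5.56 CPM ± 1.34, and the mast cell carboxypeptidase gene Cpa3 fell 7.03-fold. Camera passed this list (adjusted p = 4.86e-13), and the adjusted p was 0.195 with an estimated correlation. In the dendritic cell list, 14 of 18 tested genes fell and 2 rose (14 and 2 adjusted over the list alone), with a median of -1.94. Among them Cd74, the invariant chain of MHC class II, fell from 33.3 CPM ± 7.81 to 3.32 CPM ± 0.777 (adjusted p = 6.39e-05), and the class II genes H2-Aa and H2-Ab1 fell 8.43-fold and 5.19-fold. The 2 that rose, Tcf4 (log2 0.45) and Zbtb46 (log2 1.02), were chosen after their values were seen (list camera adjusted p = 4.86e-13, and adjusted p = 0.211 with an estimated correlation). In the monocyte-macrophage list 10 of 14 fell (10 adjusted over the list alone). Ccr2, the receptor for monocyte egress from the marrow, fell from 162 CPM ± 32.7 to 32.2 CPM ± 1.19 (5.03-fold, adjusted p = 5.53e-05), Ctss fell 3.41-fold and Csf1r fell 3.06-fold (list camera adjusted p = 5.7e-12, and adjusted p = 0.195 with an estimated correlation). The gene models of Cx3cr1, which fell 3.13-fold, and of Csf1r overlap other genes, so their counts are less certain. In these 3 lists between 8 and 15 members fell whichever library was left out.

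Erythroid genes were higher in NHD13. Of 23 tested members 18 rose and 1 fell (21 and 1 adjusted over the list alone), with a median log2 change of 1.16. Klf1, the erythroid Krüppel-like factor, rose from 68.9 CPM ± 2.97 to 157 CPM ± 40.1 (2.29-fold, adjusted p = 0.00221), Zfpm1, which encodes a cofactor of GATA1, from 62.1 CPM ± 6.7 to 164 CPM ± 34.5 (2.64-fold, adjusted p = 0.000794), and Mt2 and Tspan33 rose 2.59-fold and 2.4-fold. The member that fell, Nfe2 (log2 -0.22, adjusted p = 0.0296), was named after its values were seen, and its call was lost without any one library other than NHD13 replicate 1. The list passed camera (adjusted p = 5.69e-11) but neither fry (adjusted p = 0.0557) nor camera with an estimated correlation (adjusted p = 0.451). The libraries were not alike: the median of the erythroid members lay 0.477 log2 units above the WT mean in NHD13 replicate 1, against 1.42 and 1.41 in NHD13 replicates 2 and 3. The calls of Klf1, Tspan33 and, in the platelet list, Plek and F2r were lost with the Y-linked share as a covariate. Among 21 tested megakaryocyte and platelet genes 2 rose and 5 fell (3 and 5 adjusted over the list alone), with Itga2b falling 2.08-fold, Mmrn1 5.61-fold and Plek 1.8-fold and F2r rising 1.63-fold, and camera was not passed (adjusted p = 0.425, and 0.82 as the adjusted p with an estimated correlation). The other members that passed, Pf4 (log2 1.13), Itgb3 (-0.56) and Cd9 (-0.57), were chosen after their values were seen, and 1 rose without WT replicate 2, WT replicate 3 or NHD13 replicate 2.

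Calls of granulocyte genes changed with the libraries included. Of 20 tested granulocyte-monocyte progenitor genes 4 fell, Irf8 (3.53-fold), Csf1r, Fcgr3 (1.8-fold) and Ly6c2 (1.35-fold) (3 adjusted over the list alone). Without NHD13 replicate 1, 19 of the 20 fell, 20 fell without replicate 1 of both groups, a setting chosen after seeing the data, and 7 fell under upper-quartile scaling. The median of the list relative to the WT mean was 0.0335 in NHD13 replicate 1, against -0.632 and -0.655 in replicates 2 and 3 (camera adjusted p = 0.000904, fry adjusted p = 0.12, and adjusted p = 0.747 with an estimated correlation). The call of Ly6c2 was lost without any one of WT replicates 1, 2 and 3 and NHD13 replicates 2 and 3, and those of Irf8, Fcgr3 and Ly6c2, and of Ltf and Retnlg in the neutrophil list, with the Y-linked share as a covariate. In the mature neutrophil list 11 of 19 fell and 2 rose (12 and 2 adjusted over the list alone). The lactoferrin gene Ltf went from 5596 CPM ± 1442 to 3027 CPM ± 462 (adjusted p = 0.00846) and Retnlg fell 2.73-fold (adjusted p = 0.0074). All falls of this list, those of Ltf and Retnlg included, were lost without NHD13 replicate 1, where 0 fell by edgeR and 3 had an unadjusted p under 0.05, while 14 fell without WT replicate 1 and 5 without WT replicate 2 or WT replicate 3. The changes themselves stayed of similar size without NHD13 replicate 1, with a list median of -0.475 against -0.581 and log2 changes of -0.77 for Ltf and -1.60 for Retnlg. Without replicate 1 of both groups 14 fell (median -0.602). With no low-count filter the calls of Ltf (adjusted p = 0.0515), Retnlg (0.0537) and Ly6c2 (0.0839) were lost. The 2 that rose were stefin A genes, BC100530 (0.561 to 161 CPM) and Stfa2l1 (0.559 to 49.3 CPM), so that the list had a median log2 change of -0.58 and a mean of 0.22. Camera gave it as lower with an adjusted p of 0.261 (0.00032 without WT replicate 1, 0.0794 as higher without NHD13 replicate 1, and 0.854 as the adjusted p with an estimated correlation). The ribosomal RNA row Rn45s, chosen after its values were seen, held 319275 counts in NHD13 replicate 1 and between 14127 and 29996 in the other libraries.

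**Figure D2:**
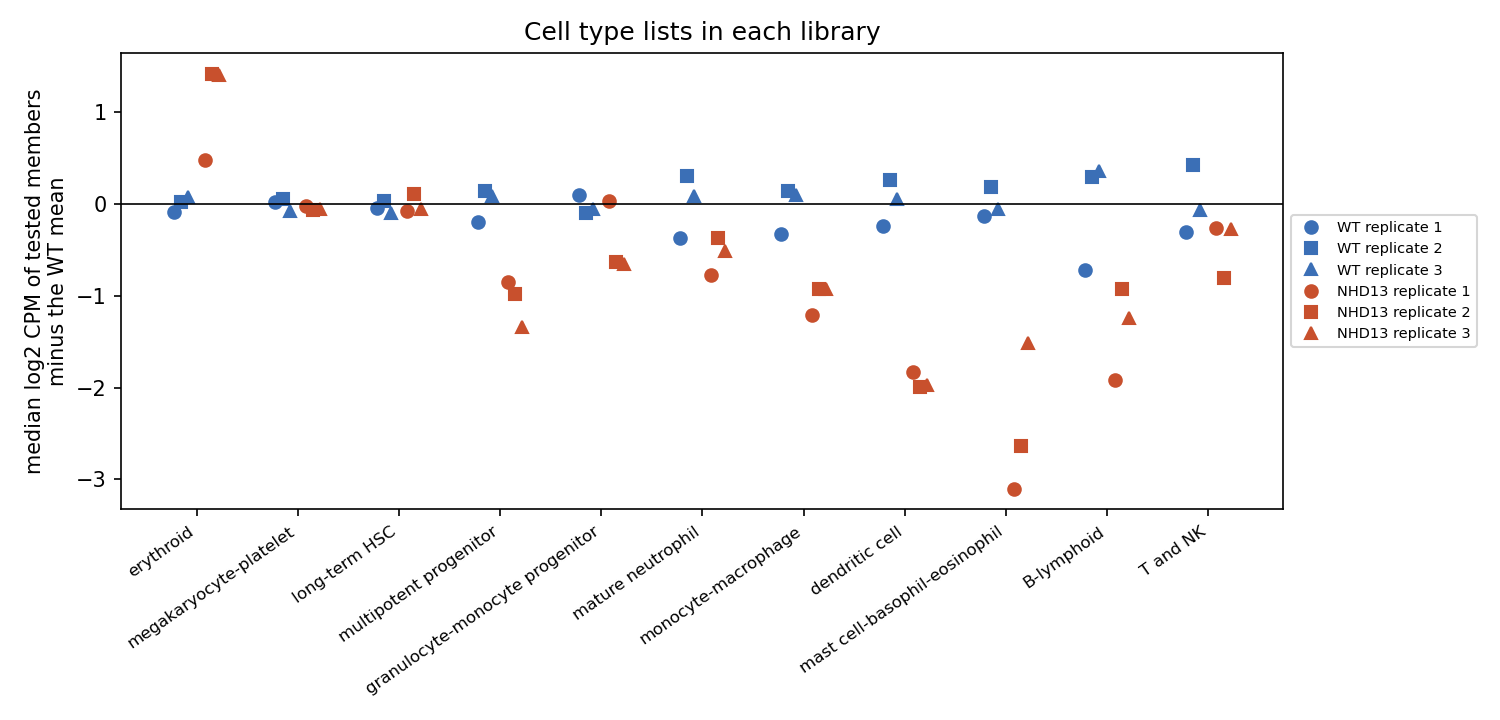
Median log2 CPM of the tested members of 11 cell type lists minus the WT mean, per library, for the 3 WT (blue) and 3 NHD13 (red) libraries. NHD13 replicate 1 lies at 0.477 for erythroid genes, below the other NHD13 libraries at 1.42 and 1.41, and at 0.0335 for granulocyte-monocyte progenitor genes, above -0.632 and -0.655.

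Most tested ribosome biogenesis genes rose by small amounts, as did a minority of the S-phase, oxidative phosphorylation and DNA repair lists. In the ribosome biogenesis list 25 of 34 rose and 1 fell (32 and 1 adjusted over the list alone), with a median log2 change of 0.34. Rrp12 rose from 54.8 CPM ± 0.499 to 82.9 CPM ± 2.55 (adjusted p = 0.000658), Nop2 1.39-fold and the RNA helicase gene Ddx21 1.45-fold. The gene that fell was Mycl1, a MYC family gene, at 3.44 CPM in WT and 0.211 CPM in NHD13. Camera passed the list (adjusted p = 3.5e-08, and adjusted p = 0.473 with an estimated correlation). When 1 library was left out 13 to 31 members rose, with 13 without WT replicate 2, 14 without WT replicate 3 or NHD13 replicate 3 and 15 without NHD13 replicate 2. The S-phase list had 12 of 30 higher (13 adjusted over the list alone), including Dut (1.37-fold), Ccne1 (1.82-fold) and Cdt1 (1.35-fold). Here camera passed (adjusted p = 0.000559), fry did not (adjusted p = 0.12), and the adjusted p was 0.747 with an estimated correlation. Without NHD13 replicate 1, 24 S-phase genes rose, and 2 to 5 rose without any one of the other 5 libraries. The call of Cdt1 was lost without NHD13 replicate 2. Oxidative phosphorylation genes rose in 10 of 52 cases (8 adjusted over the list alone), such as Atp5g1 (1.35-fold), with 31 higher without NHD13 replicate 1 and 1 to 5 without any one of the others (camera adjusted p = 0.00338, fry adjusted p = 0.12, and adjusted p = 0.808 with an estimated correlation). DNA repair genes rose in 7 of 36 cases (2 adjusted over the list alone), led by Xrcc5 (1.7-fold) and Exo1 (1.29-fold), with 17 higher and 2 lower without NHD13 replicate 1, 2 to 4 higher without any one of the others and 3 higher and 1 lower under upper-quartile scaling (camera adjusted p = 0.0145, and adjusted p = 0.564 with an estimated correlation). Of 79 ribosomal protein genes 4 rose by edgeR, Rpl8, Rpl36, Rps2 and Rps27l (0 adjusted over the list alone, and 10 at an unadjusted p under 0.05), with 23 without NHD13 replicate 1, at most 1 without any other library and 2 under upper-quartile scaling (camera adjusted p = 0.192, and 0.86 as the adjusted p with an estimated correlation). The calls of Rpl8, Rpl36 and Rps27l were lost without any library other than NHD13 replicate 1, and that of Rps2 without any other than WT replicate 3 and NHD13 replicate 1. Those of Rpl36 and Rps27l were also lost under upper-quartile scaling (adjusted p = 0.0582 and 0.0519). With the Y-linked share as a covariate, the calls of Nop2, Ddx21, Dut, Ccne1, Cdt1, Atp5g1, Xrcc5, Exo1 and the 4 ribosomal protein genes were lost, and that of Rrp12 was kept.

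The adhesion, leukaemia surface antigen, NF-kB and TGF-beta lists passed camera as lower, and none of them did so with an estimated correlation. Of 21 tested adhesion and homing genes 11 fell and 2 rose (13 and 2 adjusted over the list alone), with Vcam1 followed by Selplg (1.88-fold), the ligand of selectins, and the integrin gene Itgb7 (2.85-fold). The 2 that rose, Itga4 (log2 0.32) and Itga5 (log2 0.49), were chosen after their values were seen, and 7 fell without WT replicate 2 (list camera adjusted p = 1.71e-05, and adjusted p = 0.195 with an estimated correlation). Among 20 leukaemia stem cell surface antigens 9 fell and 1 rose (9 and 1 adjusted over the list alone). Il3ra, the receptor chain for interleukin 3, fell 2.29-fold, Cd244 2.87-fold and Cd93 2.27-fold, and the gene that rose was Cd99l2 (log2 0.70), named after its values were seen (list camera adjusted p = 0.0106, and adjusted p = 0.316 with an estimated correlation). The rise of Cd99l2 was seen in the full set and without NHD13 replicate 1, where 3 members rose, and was lost without any other library. In the NF-kB and inflammatory list 8 of 23 fell and 1 rose (11 and 1 adjusted over the list alone), led by the inflammasome gene Nlrp3 (3.96-fold) and Il1r1 (2.23-fold). Without NHD13 replicate 1, 16 fell. Only 3 fell without WT replicate 2, WT replicate 3, NHD13 replicate 2 or NHD13 replicate 3, and the rise of Tnfaip2 (1.54-fold) was lost without any library other than NHD13 replicate 1 (list camera adjusted p = 0.00454, and adjusted p = 0.473 with an estimated correlation). In the TGF-beta list 6 of 22 fell and 1 rose (6 and 1 adjusted over the list alone). Bmpr1a was followed by Ltbp3 (4.55-fold) and Acvr1 (2.79-fold), and Eng, which rose (log2 0.60), was named after its values were seen (list camera adjusted p = 0.00998, and adjusted p = 0.473 with an estimated correlation). Without NHD13 replicate 1, 11 fell and 3 rose, and without any one of the other 5 libraries 4 fell and the call of Eng was lost. The calls of Selplg, Itgb7, Il3ra, Cd244, Cd93, Nlrp3, Il1r1, Tnfaip2, Ltbp3 and Acvr1 were lost with the Y-linked share as a covariate.

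The other lists did not pass camera. Interferon response genes split, with 13 of 39 higher and 7 lower (15 and 8 adjusted over the list alone). Oasl1 rose 4.02-fold, Isg15 2.98-fold and Oas2 2.25-fold, and Ifitm1 fell 2.77-fold (camera adjusted p = 0.0785 in the full set, 0.0331 without NHD13 replicate 1, 0.0115 without WT replicate 3, and 0.82 as the adjusted p with an estimated correlation). Without WT replicate 1, WT replicate 2, NHD13 replicate 2 or NHD13 replicate 3, 4 or 5 of them rose, and 3 fell without WT replicate 2 or WT replicate 3 and 4 without NHD13 replicate 2 or NHD13 replicate 3. CDK inhibitor and quiescence genes were lower in 6 and higher in 1 of 17 (7 and 1 adjusted over the list alone), with Cdkn2c falling 1.72-fold, Cdkn1b 1.27-fold and Btg1 1.42-fold (camera adjusted p = 0.0727, fry adjusted p = 0.0293, 0.0221 without WT replicate 1, 0.0303 without NHD13 replicate 2, 0.049 with the stricter filter, and 0.451 as the adjusted p with an estimated correlation). The 1 that rose was Foxo3 (1.34-fold), whose call was lost without NHD13 replicate 2, while 2 rose without NHD13 replicate 1, and 3 members fell without WT replicate 2, WT replicate 3 or NHD13 replicate 3. Of 21 immediate early genes 4 fell and 1 rose (3 and 1 adjusted over the list alone), with Klf4 falling 3.2-fold, Fos 2.18-fold and Klf6 1.41-fold. There were 8 lower without NHD13 replicate 1 and 2 lower without WT replicate 2, WT replicate 3 or NHD13 replicate 3 (camera adjusted p = 0.0777, 0.0331 without NHD13 replicate 1, 0.0266 without WT replicate 1, 0.049 with the stricter filter, and 0.747 as the adjusted p with an estimated correlation). Without replicate 1 of both groups, a setting chosen after seeing the data, the camera adjusted p of the immediate early list was 0.0144. The fourth of its genes that fell, Btg2 (log2 -0.47), was chosen after its values were seen, and 6 fell under upper-quartile scaling and without WT replicate 1. The 1 that rose was Jund (1.5-fold), whose call was lost without WT replicate 1, WT replicate 3, NHD13 replicate 2 or NHD13 replicate 3. That of Klf6 was lost without WT replicate 2, WT replicate 3 or NHD13 replicate 3. With the Y-linked share as a covariate, the calls of Ifitm1, Cdkn2c, Cdkn1b, Btg1, Foxo3, Fos, Klf6 and Jund were lost.

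Wnt and Notch genes went both ways, 3 of 24 higher and 5 lower (3 and 5 adjusted over the list alone). The Notch ligand gene Jag1 fell from 5.38 CPM ± 1.1 to 0.119 CPM ± 0.107 (adjusted p = 0.00022), while the Notch target genes Hes1 and Nrarp rose 5.7-fold and 3.22-fold. Fzd6 fell 4.11-fold, and Axin2 (log2 -3.18), Fzd4 (-2.76), Notch1 (-0.46) and Ccnd1 (0.84) also passed and were chosen after their values were seen (list camera adjusted p = 0.213, fry adjusted p = 0.0265, and 0.564 as the adjusted p with an estimated correlation). Of 21 apoptosis regulators 3 rose and 5 fell (4 and 5 adjusted over the list alone), with Bcl2, which blocks cell death, down from 67 CPM ± 2.12 to 22 CPM ± 10.8 (adjusted p = 0.0039). Pmaip1 rose and Casp1, Birc3 and Fas also fell. Bcl2l11, which rose (log2 0.49), and Casp8, which fell (log2 -0.32), were chosen after their values were seen. The call of Casp1 was lost without WT replicate 2, WT replicate 3, NHD13 replicate 2 or NHD13 replicate 3. That of Fas was lost without WT replicate 2, WT replicate 3 or NHD13 replicate 3, and that of Pmaip1 without WT replicate 1, WT replicate 2, WT replicate 3 or NHD13 replicate 2. Among these genes 1 rose without WT replicate 1, and 1 or 2 rose and 2 or 3 fell without WT replicate 2, WT replicate 3, NHD13 replicate 2 or NHD13 replicate 3, against 5 rising and 9 falling without NHD13 replicate 1 (list camera adjusted p = 0.558, and 0.82 as the adjusted p with an estimated correlation). Among 24 p53 targets Sesn2, Pmaip1 and Aen (log2 0.30) rose and Trp53inp1, Fas and Btg2 fell (3 and 2 adjusted over the list alone), with Aen and Btg2 chosen after their values were seen. Without WT replicate 2, 0 passed by edgeR (4 higher and 2 lower at an unadjusted p under 0.05), and without WT replicate 3, 0 passed (3 higher and 4 lower unadjusted). Further, 1 rose without WT replicate 1, 3 fell and the rises were lost without NHD13 replicate 2, and 1 rose and the falls were lost without NHD13 replicate 3. The call of Sesn2 was lost without any library other than NHD13 replicate 1, and that of Trp53inp1 without any other than WT replicate 1 and NHD13 replicate 2. Without NHD13 replicate 1, 4 rose and 6 fell (camera adjusted p = 0.788, and 0.854 as the adjusted p with an estimated correlation). Of 40 MDS and AML driver genes 4 rose and 6 fell (2 and 5 adjusted over the list alone). Prpf8 rose 1.25-fold, as did Ezh2, Trp53 and Npm1 by log2 0.20, 0.28 and 0.26, chosen after their values were seen, and Idh1 and Idh2 fell 1.71-fold and 1.39-fold. The list had 10 higher and 11 lower without NHD13 replicate 1 and 1 higher and 3 lower without WT replicate 2, WT replicate 3, NHD13 replicate 2 or NHD13 replicate 3. Under upper-quartile scaling or total counts 2 rose. The median of this list was 0.025 (-0.0181 under upper-quartile scaling) and its mean -0.135 (camera adjusted p = 0.781, and 0.854 as the adjusted p with an estimated correlation). The calls of Fzd6, Nrarp, Casp1, Bcl2, Birc3, Sesn2, Pmaip1, Trp53inp1, Fas, Prpf8, Idh1 and Idh2 were lost with the Y-linked share as a covariate.

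Lineage transcription factors were higher in 7 and lower in 8 of 29 cases (7 and 12 adjusted over the list alone), with Klf1 and Zfpm1 higher and Irf8 and Sox4 lower. The number of falls was 17 without NHD13 replicate 1, 2 without WT replicate 2 or WT replicate 3, 3 without NHD13 replicate 2 and 5 without NHD13 replicate 3 (camera adjusted p = 0.768, and 0.869 as the adjusted p with an estimated correlation). In the G2-M list 3 of 32 rose and 1 fell (2 and 1 adjusted over the list alone), with Plk1, Ccnb1 and Ccna2 up 1.28-fold, 1.3-fold and 1.2-fold and Kif23 down 1.2-fold. In this list 12 rose without NHD13 replicate 1 and 1 without WT replicate 2 or WT replicate 3, while all 3 rises were lost without NHD13 replicate 2 (3 at an unadjusted p under 0.05 by edgeR; Plk1 adjusted p = 0.0503) (camera adjusted p = 0.0837, 0.0187 without WT replicate 1, and 0.82 as the adjusted p with an estimated correlation). Camera also passed the G2-M list without replicate 1 of both groups (adjusted p = 0.0209), a setting chosen after seeing the data. The call of Ccnb1 was lost without WT replicate 2 or WT replicate 3, and that of Ccna2 without any library other than NHD13 replicate 1 and under upper-quartile scaling (adjusted p = 0.0545). Heat shock and chaperone genes rose in 6 of 26 cases (6 adjusted over the list alone), such as Hsph1 (1.83-fold) and Hspd1 (1.47-fold), and 0 fell by edgeR (1 at an unadjusted p under 0.05, and 1 by DESeq2). There were 7 higher and 12 lower without NHD13 replicate 1 (camera adjusted p = 0.374 as higher and 0.254 as lower without NHD13 replicate 1, and 0.86 as the adjusted p with an estimated correlation). Glycolysis genes rose in 2 and fell in 8 of 26 cases (2 and 8 adjusted over the list alone). Hk1 rose 1.55-fold and Pfkm 2.08-fold. Of the falls 0 passed by edgeR without WT replicate 2, WT replicate 3 or NHD13 replicate 2 (8, 8 and 9 lower at an unadjusted p under 0.05), 1 without NHD13 replicate 3, 3 without WT replicate 1 and 12 without NHD13 replicate 1, where 4 rose (camera adjusted p = 0.322, and 0.82 as the adjusted p with an estimated correlation). The calls of Klf1, Irf8, Sox4, Plk1, Ccnb1, Ccna2, Kif23, Hsph1, Hspd1, Hk1 and Pfkm were lost with the Y-linked share as a covariate. Of the stromal and endothelial list, 3 of 17 genes in the table were abundant enough to test and 0 passed by edgeR or by DESeq2, with 1 at an unadjusted p under 0.05 by edgeR. Pdgfrb was at 10.7 CPM in WT and 7.43 CPM in NHD13 (adjusted p = 0.0712, and 0.0106 without NHD13 replicate 1).

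In all, 18 of 36 lists passed camera, 8 as higher and 10 as lower, 16 passed fry, and HoxA alone passed with an estimated correlation. The HoxA list includes genes that needed NHD13 to enter the test. Splits of the 6 libraries that mix the groups gave up to 23 lists, so the count of 18 does not by itself mark a group difference. Lists share members, and the granulocyte, monocyte and dendritic cell lists have Irf8 or Csf1r in common. The direction camera gave, past the threshold in neither case, turned from lower to higher for Hox cofactors and lineage transcription factors without NHD13 replicate 1 (adjusted p = 0.999 for both). It also turned for long-term HSC markers without NHD13 replicate 2 (adjusted p = 0.953), and with the stricter filter for Hox cofactors (0.916) and for Wnt and Notch genes (0.889). With the replicate number as a block it turned to higher for lineage transcription factors (camera adjusted p = 0.991). For heat shock and chaperone genes it turned to lower without NHD13 replicate 1 (0.254) and without replicate 1 of both groups (0.504), the latter chosen after seeing the data.

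**Figure D3:**
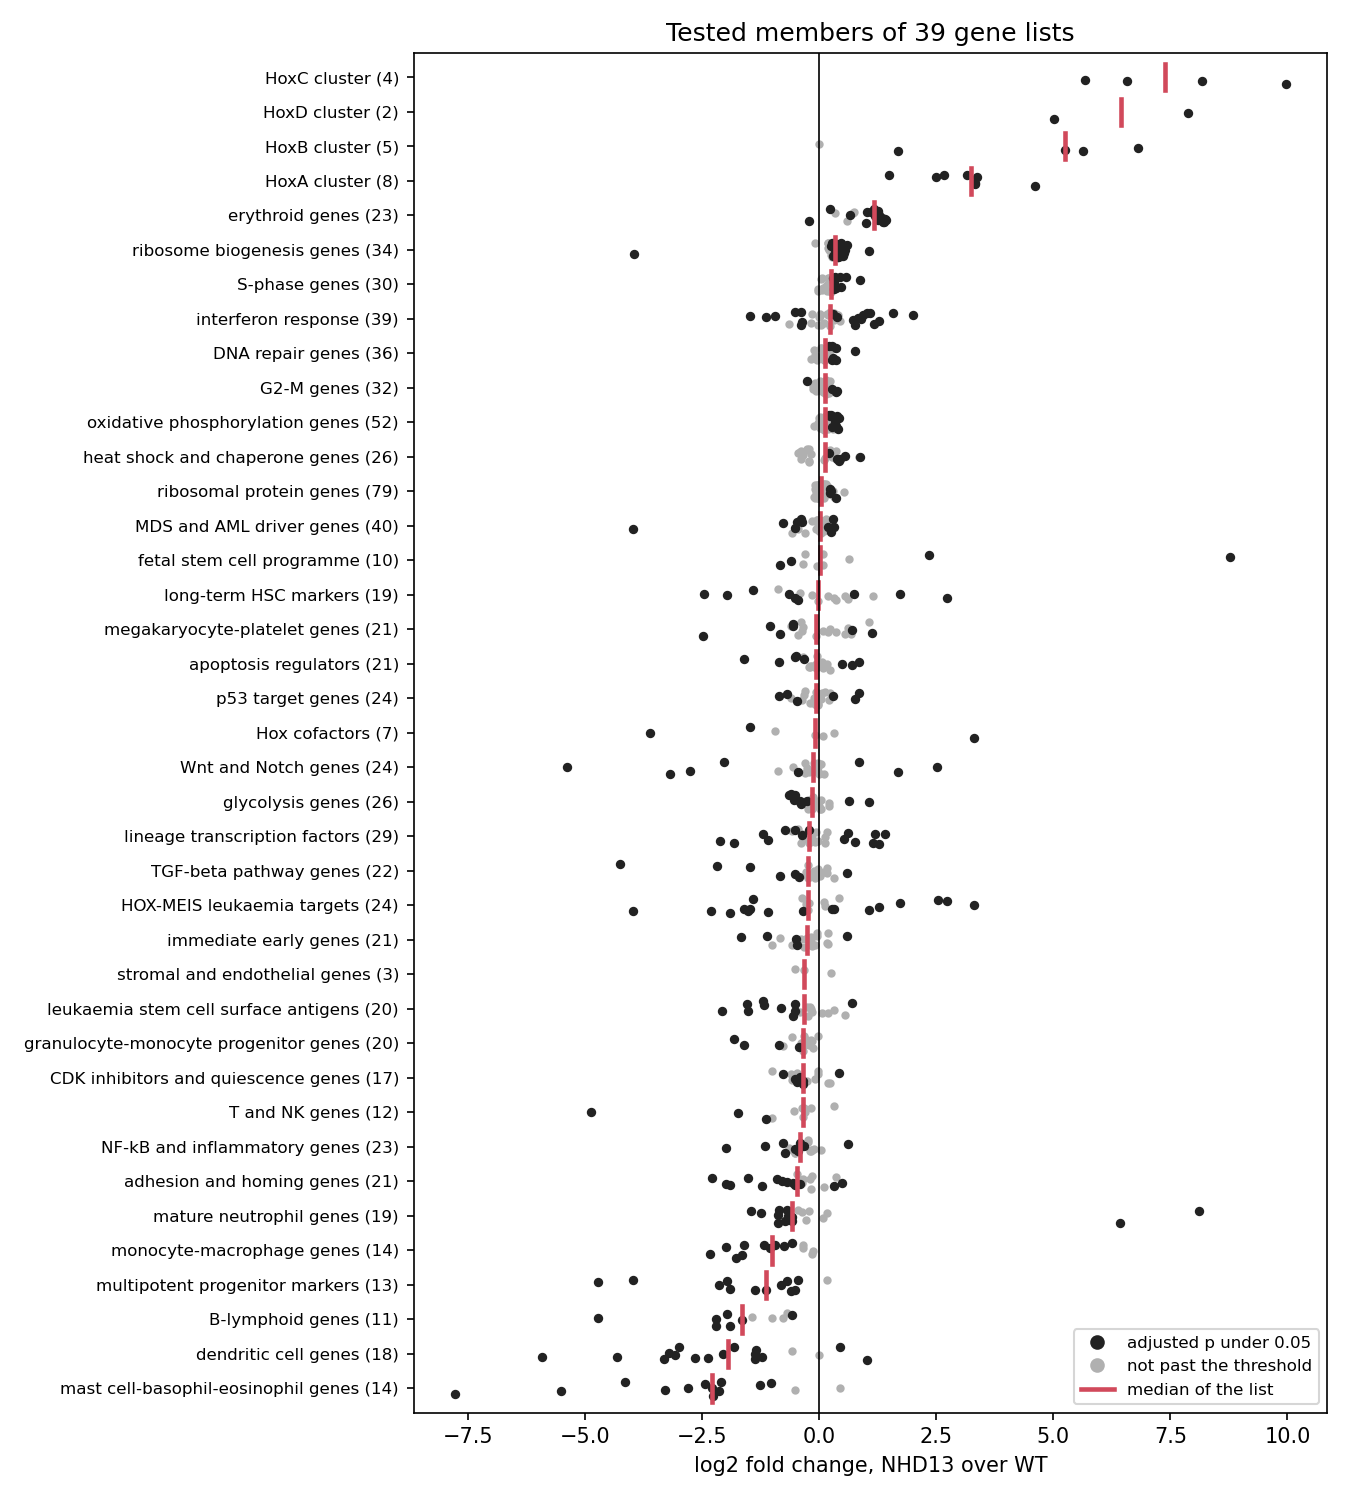
Log2 fold changes (NHD13 over WT) of the tested members of each gene list, with the number tested in brackets, black points for genes past an adjusted p of 0.05, grey points for the rest and a red bar for the median. The Hox clusters lie at the top, with a HoxA median of 3.24, and the mast cell, basophil and eosinophil list at the bottom, with a median of -2.28.

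Transcripts of the sex chromosomes differed between libraries of one group. Xist, the RNA of the inactive X chromosome in females, was at 463, 1020 and 1078 CPM in WT replicates 1 to 3 and at 2.55, 1.95 and 683 CPM in NHD13 replicates 1 to 3. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together were at 192, 110 and 113 CPM in WT and at 252, 280 and 176 CPM in NHD13. All WT libraries and NHD13 replicate 3 thus held both kinds of RNA, and NHD13 replicates 1 and 2 held Y-linked RNA with Xist under 3 CPM. Eif2s3y, Kdm5d and Uty passed the threshold as higher in NHD13 (3 of 5 tested sex genes, and 4 adjusted over the list alone), and all of these calls were lost without WT replicate 2, WT replicate 3, NHD13 replicate 1 or NHD13 replicate 2. Ddx3y passed without WT replicate 1 (adjusted p = 0.013) or NHD13 replicate 3 (0.0476), and Xist was lower without NHD13 replicate 3 (8.61e-05) and by limma-voom (0.0276). With no low-count filter the calls of Eif2s3y (adjusted p = 0.0601), Kdm5d (0.103) and Uty (0.139) were lost, and that of Uty also with the stricter filter (0.0531). Without genes on chromosomes X and Y, 1733 genes were higher and 1778 lower.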

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

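The settings without genes on chromosomes X and Y, without replicate 1 of both groups and with the Y-linked share as a covariate were chosen after seeing the data. No gene changed its direction between calls in any setting tried. Counts of higher and lower genes stayed within 1.5 times 1799 and 1839 under other scalings (1770 and 1835 with DESeq2 size factors, 1664 and 1947 with total counts), both low-count filters, DESeq2, limma-voom and estimation without the robust option. Upper-quartile factors gave 1427 and 2132, so that the share of higher genes went from 49.5% to 40.1%. Removing the 20 most abundant genes from the totals moved nothing and says nothing. The counts were 141 and 443 in the test against a 1.5-fold change and 687 and 838 at an adjusted p under 0.01, both stricter by construction. With the Y-linked share as a covariate they were 111 and 175, and without replicate 1 of both groups 3244 and 3245. Leaving out single libraries gave 760 to 3012 higher and 957 to 2966 lower genes, with the most in both cases without NHD13 replicate 1. Fewer libraries enter those fits, which alone does not account for the rise without NHD13 replicate 1. That library stood apart from its group, with a chi-square per degree of freedom of 28.57 and 28.11, against 3.459 between NHD13 replicates 2 and 3. The cause of the spread was not otherwise tested. With the replicate number as a block, 2007 genes were higher, 2233 lower and 20 lists past the threshold, newly the interferon response (adjusted p = 0.0103) and CDK inhibitor lists (0.0394), and 8 heat shock and 14 granulocyte-monocyte progenitor genes fell. The labels do not say that the numbers pair libraries. The rule used asked for a same-number correlation of deviations of over 0.1 for every pair, and these were 0.249, 0.0632 and 0.175. However, 5 of the 6 libraries correlated best with their own number. NHD13 replicate 1 was at 0.249 with WT replicate 1, against -0.0853 and -0.235 with WT replicates 2 and 3. An effect shared by libraries of one number thus stays open. Of 36 lists, 18 passed, 18 to 23 without single libraries, 16 by fry and 1 by camera with an estimated correlation. Of 3326 values of the 168 selected genes under alternatives, 3013 kept their direction and side of the threshold, 297 no longer passed, 12 newly passed and 4 reversed. Of the reversals, 3 were of Hoxb4, at 0.34 with the covariate and -0.17 to 0.13 without single libraries, not called in any of these, and the cause was not tested. The other was Ddx3y, at -0.11 with the covariate, which is built from it and 3 other Y-linked genes, so this says nothing of the gene. Depth limits the low genes: 31 called genes had at most 3 counts in one group.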

Other observations

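Only the test of genes near the stefin A cluster and the test with the Y-linked covariate had their expected outcomes written before their result was seen; all other tests here were chosen after the result was seen, and the covariate itself was added after the expression of NHD13 replicate 3 had been examined.

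Beyond the Hox genes, several genes went from near 0 counts to clear expression in NHD13, chosen here after their values were seen. Among 31 called genes with at most 3 counts in one group, 19 were higher in NHD13 and 12 lower, and 8 of the 19 were Hox genes. Epha3, an ephrin receptor gene, went from 0.0232 CPM ± 0.0402 to 6.46 CPM ± 3.52 (n = 3 each, edgeR adjusted p = 0.00102), a ratio of 258 with a 95% counting interval of 45.9 to 10200. Slit2, which encodes a guidance ligand, and Zfpm2, a cofactor of GATA factors, had 0 counts in WT and were at least 32.3-fold and at least 69.7-fold higher in NHD13, at 2.36 CPM ± 1.42 and 5.25 CPM ± 2.66. The membrane protein gene Tmem47 rose to 5.86 CPM ± 1.86 (ratio 238, interval 42.3 to 9430). In the other direction, Gpc4, a heparan sulfate proteoglycan gene, fell from 4.69 CPM ± 0.457 to 0.0482 CPM ± 0.0418 (adjusted p = 6.39e-05), Rnf217 fell from 5.84 CPM ± 1.18 to 0.025 CPM ± 0.0433 (adjusted p = 7.48e-05) and Epha2, another ephrin receptor gene, fell from 2.03 CPM ± 0.993 to 0.023 CPM ± 0.0399.

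The 7 stefin A genes between 36156811 and 36455392 on chromosome 16 (mm10) summed to 4.03 CPM ± 0.964 in WT and 583 CPM ± 258 in NHD13. More maturing neutrophils as the source is argued against, since the 17 other neutrophil genes had a median log2 change of -0.662 and a highest value of 0.173 (median -0.532 without NHD13 replicate 1), far below the stefin A median of 7. A shift of reads only among these 7 copies is argued against, since each rose by a log2 change of at least 6.42. Their sum, taken after these rises were seen, therefore had to rise (145-fold) and adds nothing. A shift from copies outside these 7 was not examined. A chromosome segment of another origin around the cluster may still contribute: 12 of 32 tested neighbours within 2 Mb changed (37.5%, exact 95% interval 21.1 to 56.3, against 30.3% of all genes, one-sided Fisher's exact p = 0.239), which leaves it open. Regulation by the fusion was not tested apart from the comparison of the groups.

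The erythroid list rose by a median log2 change of 1.16, least in NHD13 replicate 1. TMM factors ran only from 0.987 to 1.009, and the mature neutrophil list took 4.99% of counts in WT and 3.23% in NHD13. These shifts are small beside a median of 1.16, which argues against scaling set by abundant myeloid genes as the source. The lowest median under 3 other scalings was 1.12, but with such factors it could hardly have moved. A loss of neutrophils that raises every other cell type alike is argued against by the medians of 6 other lists. The highest was -0.018 for the long-term HSC markers and the lowest -2.28 for mast cell, basophil and eosinophil genes. With 1 library left out, the median of the long-term HSC markers ran from -0.177 (without NHD13 replicate 1) to 0.179 (without WT replicate 3), the highest of these lists, and the erythroid median from 1 to 1.39. A larger share of erythroid precursors in the sorted NHD13 cells may account for the pattern as a hypothesis: 87% of the 23 tested genes lay within 1.5-fold of their median change. A change of erythroid gene expression within the stem cells themselves predicts no value that these bulk counts exclude, and the sort gate is not given in the sources used here.

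Over the 6 libraries, Xist fell as the summed Y-linked genes rose (r = -0.988, exact permutation p = 0.00694 over 720 orders, Spearman's rho = -0.943, exact permutation p = 0.0167, both two-sided, 1 relation computed, so that the Benjamini-Hochberg values are the same), and r was -0.981 without NHD13 replicates 2 and 1, the libraries farthest from the median. Libraries pooled from male and female mice may account for this, as 4 of the 6 held both kinds of RNA. As the sole cause of the changed genes the sex mix is argued against: with the Y-linked share as a covariate a median of 99.1% of the log2 change was left over 3514 changed autosomal genes (quartiles 84.8 and 112), with 100% of them in the same direction. Their median log2 change went from 0.527 to 0.52 in size and their median SE from 0.118 to 0.191, as 57.8% of the variance of the covariate lay between the groups, so the calls ended by a wider error, and 111 higher and 175 lower genes passed. Whether the sex mix adds to single genes stays open where its effect and that of the fusion overlap.

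The 6 libraries can be split into groups of 3 in 10 ways, so the share of splits is never under 0.1. The real split gave 3638 changed genes and the highest other gave 0 by edgeR (1 of 10 as large, the real one), with 5177 genes at an unadjusted p under 0.05 in the real split and at most 1105 in another. Every other split has WT and NHD13 libraries on both sides, so the difference between the groups widens the spread within each side. Their 0 therefore does not measure what a grouping of unrelated libraries would give. For gene lists the real split gave 18 and the highest other 23, and 3 of 10 splits gave as many. Across genes, which are not independent replicates, the log2 change had a Spearman correlation of 0.0737 with the GC content of the longest annotated transcript and -0.0311 with its length, over the 99% of tested genes with a value.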
